A study of Spongilla lacustris with 18 samples.

How the data were processed

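Juvenile freshwater sponges, Spongilla lacustris, were grown for 9 days at 18 °C per the labels' protocols, exposed to 37.5 µM tryptamine or to 0.03% DMSO as vehicle, and taken as whole bodies for polyA RNA sequencing. Samples were taken after 1 h, after 4 h, or after 4 h followed by a washout and 24 h of recovery, which gives 6 groups of 3 libraries. The labels give each library a replicate number but do not say whether same-numbered libraries shared a culture or a day, nor that replicates were separate cultures or clones. The p-values therefore measure only the spread between these samples, part of which may be technical.

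The deposited table holds raw counts of read pairs per gene, made by the authors with featureCounts 2.1.1 per the file headers, without normalization. Per the file headers, pairs were counted without regard to strand, both ends had to be mapped, chimeric pairs were left out and reads mapping to several places were not counted. Per the submitters' processing notes the reads were aligned with STAR, whose version is not given in the sources used here. The features are genes of an assembled transcriptome, named by component and gene number, and no genome or coordinates were used here. The table holds 39562 genes, of which 4925 had no count in any library, 9765 carried a usable name and 7930 a symbol. Names come from the deposited table, where a gene can carry several symbols of vertebrate relatives, and they state similarity, not identity. Reads shared between near-identical copies were not counted, so the levels of families with many named genes are uncertain.

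Everything that follows was computed from those counts with R 4.3.3. Genes were filtered with filterByExpr by group, which left 24125 tested genes, 9337 of them named. Library sizes were scaled by TMM factors, which ran from 0.854 to 1.09. One edgeR 4.0.16 quasi-likelihood model with robust dispersions was fitted to the 18 libraries with a mean per group, giving 12 residual degrees of freedom and a common biological coefficient of variation of 21%. Each contrast was tested two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Tryptamine was compared with time-matched DMSO at each time, the effects at successive times were compared by interaction contrasts, and the DMSO groups were compared over time. Levels are TMM-scaled CPM (counts scaled by the library total) with the SD over 3 libraries.

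The groups, the comparisons, the tests, 23 gene lists, most of the alternatives and the rule for named genes were set before the data were examined. A gene was named when its adjusted p was under 0.05, its mean was at least 20 counts over the 6 libraries compared, the 3 tryptamine libraries lay on one side of the 3 DMSO libraries and the table gave a usable name. The 8 largest rises and the 8 largest falls were taken, with the 2 members of smallest adjusted p from each list. Where fewer than 3 genes qualified, the 3 named genes with the smallest p were taken as genes that did not pass. Lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry. The results of 1 list and of some genes are not reported here.

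Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios scaling, no filter, a stricter filter, non-robust dispersions, a fit of the compared groups alone, the replicate number as a block, fold thresholds of 1.2 and 1.5, and leaving out each library in turn. Removal of a per-library gene length trend, a fit without the 4 h libraries of number 2 and the leaving out of single libraries for the gene lists were chosen after seeing the data. The numbers were taken to pair the libraries where every pair of same-numbered libraries had correlated deviations from their group means above 0.1. This held at 1 h (0.332 to 0.402), at 4 h (0.115 to 0.191) and for DMSO at 4 h against 1 h (0.179 to 0.273), and it comes from the data and not from the labels. Within groups, the chi-square of replicate counts over its degrees of freedom was 8.27 to 48.7 in the 18 pairs, so no library was a copy of another.

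The tests were run first on simulated data with 200 changed genes. At 1 h, over 23693 simulated genes tested, 1.49% of the genes changed 1.5-fold, 34.3% of those changed 2-fold and 77.3% of those changed 4-fold were recovered. At 4 h, over 23690 genes, the shares were 5.97%, 25.4% and 81.8%, and after recovery, over 23697 genes, 7.46%, 25.4% and 75.8%. Of the 79, 79 and 74 genes called, 4, 2 and 2 were unchanged ones.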

Results

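The transcriptional response of a nerveless animal to a monoamine was followed in juvenile sponges by RNA sequencing. Tryptamine is a trace amine derived from tryptophan, and DMSO is its solvent. The 18 libraries fell into 6 groups of 3, with tryptamine and DMSO at 1 h, at 4 h and after washout and 24 h of recovery. Library totals ran from 11379345 to 23769406 counted read pairs, and the second highest total was 15798197. Each library had counts for 30384 to 32306 genes, and its 10 most abundant genes took 5.21% to 6.23% of the counts. A level of 3 counts corresponded to 0.126 to 0.264 CPM, a floor that covers counting error alone.

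The first comparison asked what tryptamine changed within 1 h. No named gene passed the test, and the 3 named genes with the smallest p were all lower with tryptamine. Guanylate cyclase c103422-g1, whose family makes the second messenger cyclic GMP, measured 46.2 ± 13.2 CPM with tryptamine and 102 ± 25.6 CPM with DMSO (SD, n = 3), a log2 difference of -1.15 (SE 0.24, edgeR adjusted p = 0.454). HEXIM2,HEXIM1 c104215-g3, related to inhibitors of transcription elongation, differed by -0.90 (SE 0.20, adjusted p = 0.65), and a gene named for galectin-8, c100695-g1, a sugar-binding lectin, by -0.86 (SE 0.20, adjusted p = 0.651). The edgeR test called 0 genes higher and 0 lower among 24125, with 1553 at an unadjusted p under 0.05, while limma-voom called 0 and 0 and DESeq2 2 higher and 14 lower. With the replicate number as a block, 1 gene was called higher and 6 lower, among them guanylate cyclase (-1.15, SE 0.17, adjusted p = 0.0302), HEXIM2,HEXIM1 (-0.91, adjusted p = 0.0391) and NFATC3,NFATC2,NFATC4,NFATC1 (-2.14, adjusted p = 0.0484), the last named after its value was seen. Without DMSO 1 h replicate 3, 5 genes were called lower.

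Among the 23 gene lists at 1 h, camera called 4 at the preset correlation, although none of their members passed the test over all genes or adjusted over the list alone. Archaeocyte and stem cell markers, genes of the sponge's motile pluripotent cells, had a median log2 difference of 0.25 with 28 of 33 members positive (adjusted p = 0.00305). Integrin adhesion and cell junction genes had a median of 0.05 (adjusted p = 0.0251). Ribosomal protein genes had a median of -0.09 with 92 of 137 members negative, and mitochondrial respiratory chain genes a median of -0.08 with 47 of 65 negative (each adjusted p = 0.0256). None of the 4 held with an estimated correlation (adjusted p = 0.967 with an estimated correlation for each). Leaving out single libraries left 1 called list without DMSO replicate 1 and 2 without DMSO replicate 2. The integrin, ribosomal and respiratory chain calls were lost without DMSO replicate 1 (adjusted p = 0.336, 0.628 and 0.336) and without DMSO replicate 2 (0.157, 0.449 and 0.343). The archaeocyte and integrin calls were lost without tryptamine replicate 1 (0.58 and 0.107), and the ribosomal and respiratory chain calls without tryptamine replicate 3 (0.563 and 0.586). In the nitric oxide and cyclic GMP list, 1 member, guanylate cyclase, was lower when adjusted over the list alone.

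The comparison at 4 h asked the same of the longer exposure, and here falls outnumbered rises. In the comparisons of tryptamine with DMSO, a fall or rise is a level below or above DMSO at the same time. Measured from DMSO at 1 h, the genes called lower had a median log2 difference of 2.09 in DMSO at 4 h. In tryptamine at 4 h it was 0.26, so the difference lay mainly in a higher level in DMSO. Selection of these genes on both 4 h groups favours such a gap. RSAD2 c4918-g1, whose vertebrate relative viperin is an interferon-induced antiviral enzyme, measured 0.959 ± 0.315 CPM with tryptamine and 9.67 ± 3.00 CPM with DMSO (SD, n = 3), a log2 fall of -3.34 (SE 0.34, edgeR adjusted p = 9.04e-05). TRIM2 c87469-g1, of a ubiquitin ligase family, fell from 407 ± 239 to 22 ± 5.63 CPM (-4.21, SE 0.52, adjusted p = 0.000613). Synoviolin c97836-g1, named for a ubiquitin ligase of protein quality control in the endoplasmic reticulum, fell from 1080 ± 557 to 123 ± 5.48 CPM (-3.14, SE 0.32, adjusted p = 0.000101). RNF213, a giant ubiquitin ligase of antiviral and antibacterial defence in vertebrates, was the name of 4 of the 8 largest falls, with log2 changes of -2.96 (SE 0.37) for c94017-g2, -3.09 (SE 0.41) for c94017-g1, -3.20 (SE 0.44) for c105143-g1 and -3.60 (SE 0.60) for c105075-g1. That name covered 33 genes of the table, 21 of them tested and 7 called lower, and TRIM2 covered 13 genes with 12 tested, so counts in both families are uncertain where copies share sequence.

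Fewer genes were higher with tryptamine at 4 h, and by less. Measured from DMSO at 1 h, the genes called higher had a median log2 difference of 0.54 in tryptamine at 4 h and -0.58 in DMSO at 4 h. In tryptamine at 1 h it was already 0.42, so part of the difference is a lower level in DMSO at 4 h. Selection of these genes on both 4 h groups may add to that gap. KLF9 c102282-g1, a zinc finger transcription factor, measured 185 ± 11.3 CPM with tryptamine and 96.2 ± 19.2 CPM with DMSO (0.94, SE 0.16, adjusted p = 0.00279). RNF11, a RING finger protein, measured 94.3 ± 38.7 against 43 ± 1.53 CPM (1.13, SE 0.20, adjusted p = 0.00373), and EXD2 c96222-g1, an exonuclease, 7.38 ± 2.43 against 2.25 ± 0.56 CPM (1.70, SE 0.30, adjusted p = 0.00341). JMY, which promotes actin assembly, had the largest rise among named genes (2.21, SE 0.42, adjusted p = 0.0107), with 33.1 ± 25.3 against 7.15 ± 1.19 CPM. The JMY call was lost without DMSO replicate 1 (adjusted p = 0.0502) and without DMSO replicate 3 (0.0788).

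**Figure D1:**
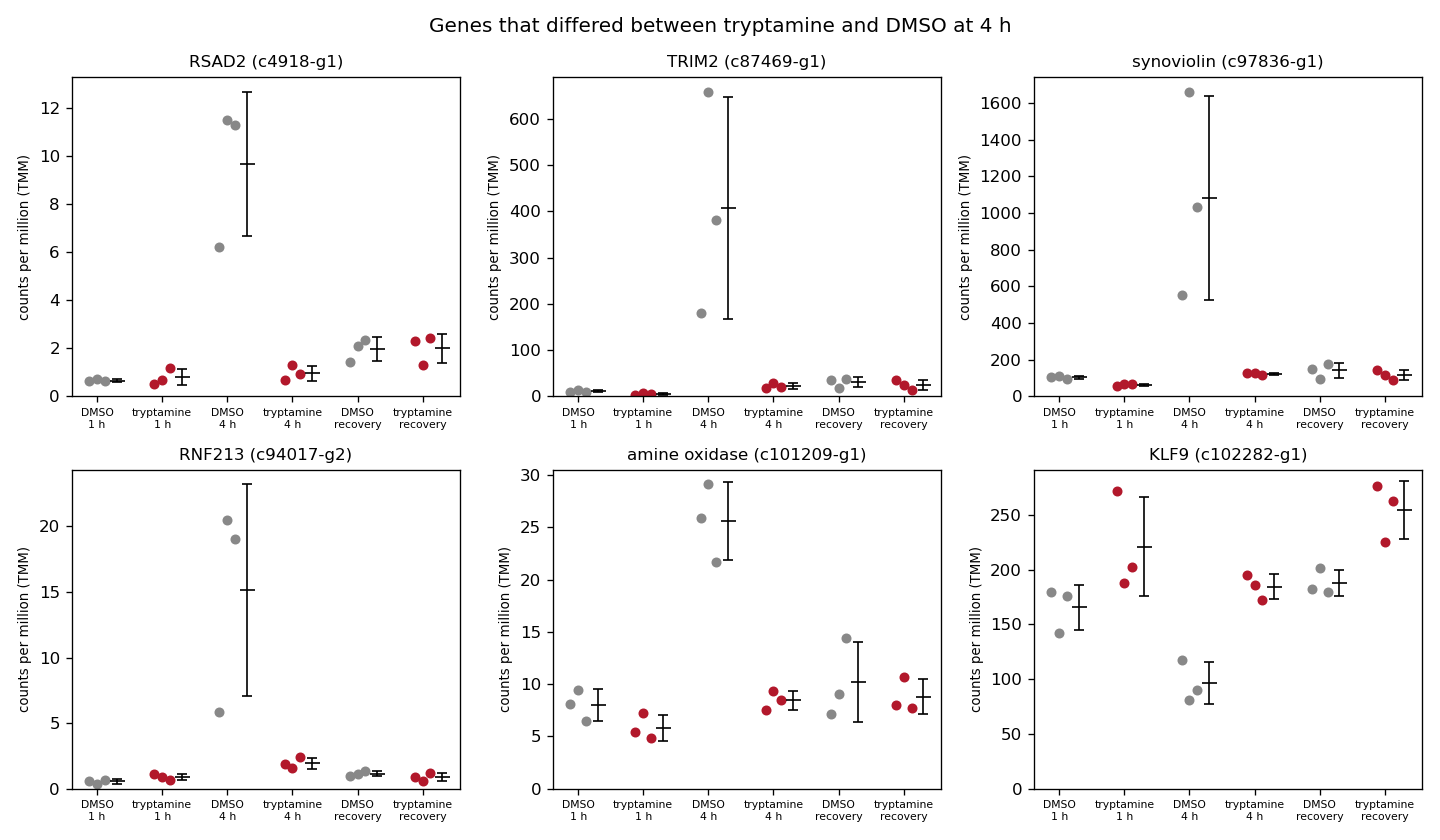
Levels of 6 genes at 1 h, 4 h and recovery in TMM-scaled CPM, with 1 point per library, grey for DMSO and red for tryptamine, and a black dash and bar for the mean and SD (n = 3). RSAD2, TRIM2 c87469-g1, synoviolin, RNF213 c94017-g2 and amine oxidase are lower with tryptamine at 4 h, and KLF9 is higher.

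In all, 57 genes were higher and 306 lower at 4 h, 1.5% of those tested, with a median absolute log2 change of 1.70 and 2830 genes at an unadjusted p under 0.05. In 358 of the 363 the groups did not overlap, which the selection of called genes favours, against 13.5% of the tested genes and a chance share of 10%. The count of higher genes was 158 with DESeq2, 31 in a fit of the compared groups alone, 126 with the replicate block, 17 without DMSO replicate 2, 111 without tryptamine replicate 1 and 38 without DMSO replicate 3. A test against a fold of 1.5 left 153 genes, and without both libraries of number 2, a choice made after seeing the data, 6 were higher and 92 lower. Among the named genes, RSAD2, TRIM2 c87469-g1, synoviolin, 3 RNF213 genes, amine oxidase, TTC28 and a scavenger receptor passed under each of 16 alternatives.

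By gene list, the innate immunity, NF-kappa-B and cell death list had 6 of 124 members lower and 0 higher at 4 h, and 6 lower and 3 higher adjusted over the list alone. Among the falls was synoviolin, which entered the list through the word apoptosis in its full name. So was CASP2,CASP1, related to proteases of inflammation and cell death, by -1.04 (SE 0.18, edgeR adjusted p = 0.00279) from 67.3 ± 21.5 to 32.7 ± 2.82 CPM. The list as a whole was not shifted (median 0.07, camera adjusted p = 0.846), while the two-directional fry test gave an adjusted p of 7.89e-06. Of 51 members of the list for monoamine synthesis, breakdown and transport, 3 were lower, also adjusted over the list alone. These included 1 of 2 tested amine oxidase genes, c101209-g1, of the enzymes that deaminate amines, which fell from 25.6 ± 3.72 to 8.46 ± 0.895 CPM (-1.60, SE 0.24, adjusted p = 0.000728). They also included WARS c103838-g4, which charges tRNA with tryptophan and makes no monoamine, at 8.23 ± 1.22 against 40.4 ± 17.3 CPM (-2.29, SE 0.36, adjusted p = 0.00232), whereas the other tested gene named WARS, c101014-g2, differed by 0.19 (adjusted p = 0.781). This list too was not shifted as a whole (camera adjusted p = 0.955), with a two-directional fry adjusted p of 4.54e-05. The lysosome and phagocytosis list had 4 of 136 members lower, among them a scavenger receptor, c104597-g4 (-2.78, SE 0.38, adjusted p = 0.000442). The choanocyte flagellum list had 3 of 151 lower, among them RSPH14, of the radial spokes (-1.59, SE 0.29, adjusted p = 0.00514), and TTC28 c101012-g1, 1 of 9 tested genes of that name, a repeat protein with no settled role in flagella (-1.80, SE 0.21, adjusted p = 0.000101).

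Camera called 1 list at 4 h, the immediate early and MAP kinase feedback genes, with a median of 0.18 and 19 of 25 members positive (adjusted p = 0.00131). The call was lost with an estimated correlation (adjusted p = 0.534 with an estimated correlation) and without tryptamine replicate 2 (adjusted p = 0.122), whereas 5 lists were called without DMSO replicate 2 or tryptamine replicate 3, and 2 without DMSO replicate 1, DMSO replicate 3 or tryptamine replicate 1. In this list 1 member, KLF9, was higher, and 4 adjusted over the list alone. Among G protein-coupled receptors 1 of 85 was lower, LGR6,LGR4, related to R-spondin receptors, at 19.1 ± 2.25 against 51.6 ± 20.1 CPM (-1.44, SE 0.26, adjusted p = 0.00455), and 3 were lower adjusted over the list alone. In another 6 lists 1 member was called: AKAP14 (kinase anchoring) and COL1A1 c100522-g2 (collagen) were lower, and a TRPA-type cation channel c102145-g2, CHST11 (chondroitin sulfation), DLG5 c99359-g1 (a junction scaffold) and ORC2 (replication origins) higher. None of these 6 passed without DMSO replicate 3 (adjusted p = 0.0802 to 0.146), and each was also lost without other single libraries.

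The comparison after recovery asked what remained or appeared a day after washout, and here rises outnumbered falls. HSPD1 c96953-g1, the mitochondrial chaperonin Hsp60, measured 668 ± 62.9 CPM after tryptamine and 323 ± 42.3 CPM after DMSO (SD, n = 3), a log2 rise of 1.05 (SE 0.23, edgeR adjusted p = 0.0324). MDN1 c102648-g1, an ATPase of ribosome assembly, rose by 1.21 (SE 0.26, adjusted p = 0.0324), from 9.14 ± 0.82 to 21.1 ± 3.38 CPM, and OXA1L c100800-g1, which inserts proteins into the inner mitochondrial membrane, by 1.14 (SE 0.24, adjusted p = 0.0324), from 15.5 ± 1.03 to 34.2 ± 4.51 CPM. RNMT, which methylates the messenger RNA cap, rose by 1.16 (SE 0.24, adjusted p = 0.0297), and POLD3, a DNA polymerase delta subunit, by 0.95 (SE 0.19, adjusted p = 0.0297). ASMT,ASMTL c100382-g1, named for the last enzyme of melatonin synthesis, rose by 0.90 (SE 0.19, adjusted p = 0.0297), from 24.1 ± 4.62 to 44.8 ± 6.29 CPM.

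Among the falls after recovery, thioredoxin c95674-g1, which reduces protein disulfides, went from 962 ± 137 to 322 ± 106 CPM (-1.58, SE 0.29, adjusted p = 0.0258), in a family of 14 genes of that name with 13 tested, so its level is uncertain. CBP c101065-g1, a sarcoplasmic calcium-binding protein, fell from 340 ± 119 to 138 ± 25.6 CPM (-1.30, SE 0.30, adjusted p = 0.042), and CAM c101992-g1, calmodulin, from 394 ± 90.8 to 199 ± 50.6 CPM (-0.98, SE 0.23, adjusted p = 0.0385). Guanylate cyclase fell from 68.6 ± 2.18 to 32.3 ± 7.19 CPM (-1.09, SE 0.24, adjusted p = 0.0324), with -0.69 (SE 0.23, adjusted p = 0.196) at 4 h. ABCC4 c73128-g1, 1 of 11 tested genes named for an exporter of cyclic nucleotides and drugs, fell by 1.23 (SE 0.26, adjusted p = 0.0324). Falls of 0.81 (SE 0.17, adjusted p = 0.0297) and 0.78 (SE 0.18, adjusted p = 0.0348) on the log2 scale were measured for IFT20 and IFT22, which carry cargo along flagella.

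**Figure D2:**
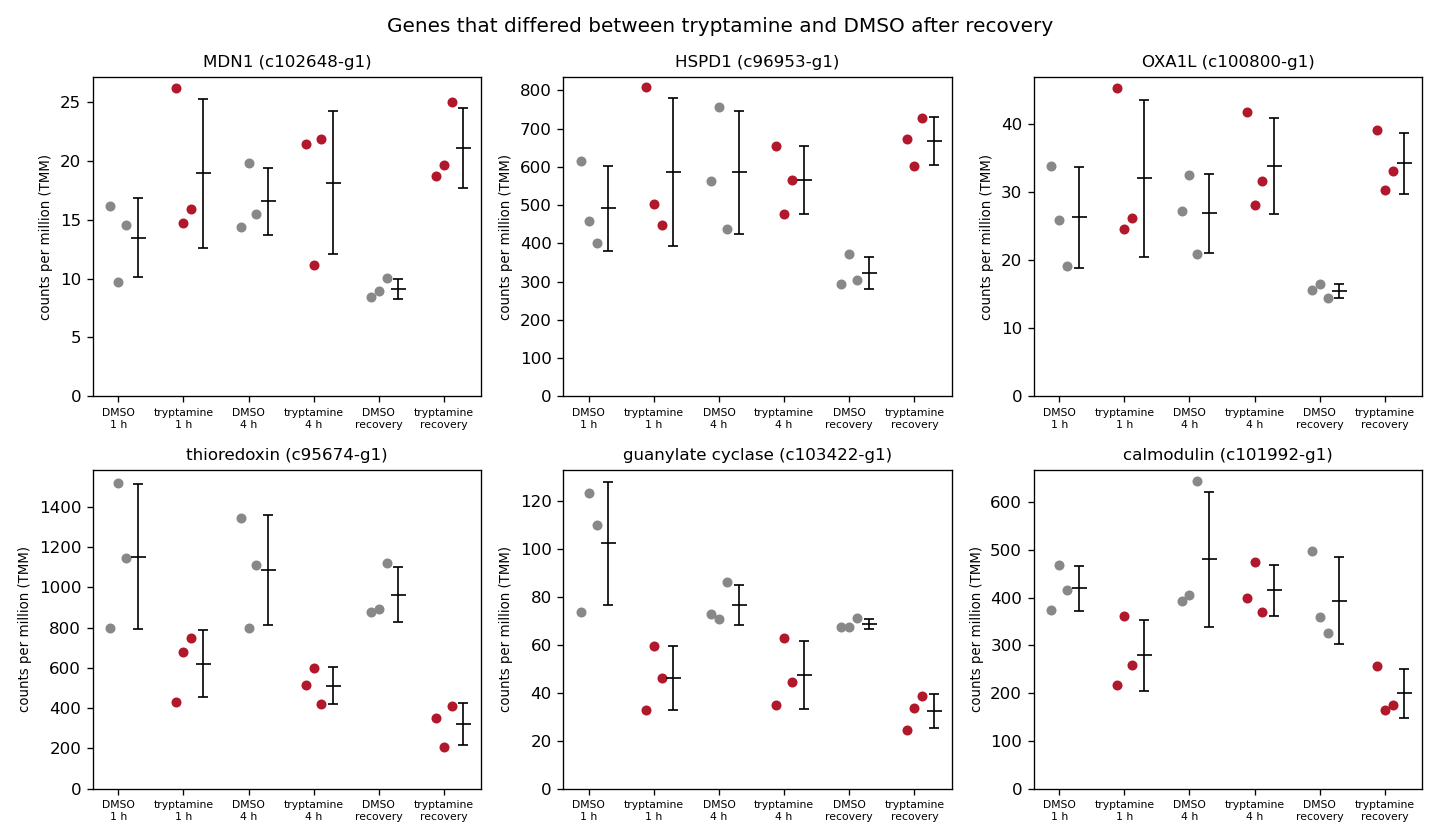
Levels of 6 genes in the 6 groups in TMM-scaled CPM, with 1 point per library, grey for DMSO and red for tryptamine, and a black dash and bar for the mean and SD (n = 3). After recovery, MDN1, HSPD1 and OXA1L are higher and thioredoxin c95674-g1, guanylate cyclase and calmodulin lower with tryptamine.

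After recovery 329 genes were higher and 120 lower, 449 in all, with a median absolute log2 change of 0.86 and 4157 genes at an unadjusted p under 0.05. In 448 of the 449 the groups did not overlap, which the selection of called genes favours, against 23.9% of the tested genes and a chance share of 10%. DESeq2 called 782 higher and 335 lower, while a test against a fold of 1.2 left 5 genes and one against a fold of 1.5 left 0. These calls lay close to the threshold, with a smallest adjusted p of 0.00566, and each of the 40 named genes lost its call without at least 3 of the 6 libraries. The counts of higher and lower genes were 57 and 74 without tryptamine replicate 1, 0 and 1 without tryptamine replicate 2, 269 and 197 without tryptamine replicate 3, 0 and 0 without DMSO replicate 1, 76 and 60 without DMSO replicate 2, and 0 and 2 without DMSO replicate 3.

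Camera called 11 of the 23 lists after recovery, none of which held with an estimated correlation. Of 85 heat shock proteins and chaperones, 15 were higher and 0 lower, and 29 were higher adjusted over the list alone (median 0.27, adjusted p = 2.8e-11, adjusted p = 0.19 with an estimated correlation). HSPD1 and HSPA14, an Hsp70 (0.87, SE 0.16, adjusted p = 0.0227), were the members with the smallest p. The endoplasmic reticulum stress list had 2 of 32 members higher and 12 adjusted over the list alone, with 1 lower (median 0.33, adjusted p = 7.35e-06, adjusted p = 0.19 with an estimated correlation). HSP90B1, the chaperone Grp94, was one of these at 1130 ± 235 against 650 ± 89.5 CPM (0.79, SE 0.20, adjusted p = 0.0462), and PDIA3, which forms disulfides, the other at 571 ± 46.3 against 352 ± 36.7 CPM (0.70, SE 0.17, adjusted p = 0.0396). Ribosomal protein genes had 129 of 137 members positive, 4 higher and 39 higher and 1 lower adjusted over the list alone (median 0.33, adjusted p = 4.22e-16, adjusted p = 0.413 with an estimated correlation). The list was named for cytosolic ribosomes but holds 45 mitochondrial ribosomal proteins, whose median was 0.43 against 0.29 for the others, and MRPS25 (0.73, SE 0.18, adjusted p = 0.0412) is one of these. The cell cycle and DNA replication list had 3 of 101 members higher, and 36 higher and 1 lower adjusted over the list alone (median 0.37, adjusted p = 1.34e-11, adjusted p = 0.19 with an estimated correlation). The proteasome list had 2 of 77 higher and 14 adjusted over the list alone (median 0.20, adjusted p = 1.21e-05, adjusted p = 0.524 with an estimated correlation). PSMD2, of its regulatory particle, rose by 0.58 (SE 0.14, adjusted p = 0.0412).

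Archaeocyte and stem cell markers had 29 of 33 members positive after recovery, 1 higher and 13 adjusted over the list alone (median 0.45, adjusted p = 2.85e-08, adjusted p = 0.322 with an estimated correlation). CELF1,CELF2, an RNA-binding protein, was the called member (1.07, SE 0.26, adjusted p = 0.0408). The mitochondrial respiratory chain was shifted up with no called member (median 0.12, adjusted p = 0.0171, adjusted p = 0.718 with an estimated correlation). Downward shifts without a called member were found for the actomyosin contractile apparatus, with 50 of 61 members negative (median -0.24, adjusted p = 0.000148, adjusted p = 0.452 with an estimated correlation), and for G protein-coupled receptors, with 71 of 85 negative (median -0.21, adjusted p = 0.000254, adjusted p = 0.336 with an estimated correlation). In both lists 0 members passed adjusted over the list alone. Nitric oxide and cyclic GMP signalling was shifted down with 17 of 20 negative, 1 lower, guanylate cyclase, and 3 adjusted over the list alone (median -0.28, adjusted p = 0.00034, adjusted p = 0.19 with an estimated correlation). Integrin adhesion and junction genes were shifted down (median -0.14, adjusted p = 0.0348, adjusted p = 0.718 with an estimated correlation), although the 1 called member, CTNNBL1, a splicing factor by function, was higher. Without tryptamine replicate 1 the integrin and respiratory chain calls were lost (adjusted p = 0.0713 and 0.0813), as they were without tryptamine replicate 2 (0.355 and 0.12). The integrin call was also lost without DMSO replicate 1 (0.542) and the respiratory chain call without DMSO replicate 3 (0.254).

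The lists that follow were not called after recovery. Choanocyte flagellum markers had a median of -0.09 (adjusted p = 0.114) with 3 members lower, and sclerocyte and biosilicification markers, with 6 tested, a median of 0.09 (adjusted p = 0.432). Calcium signalling had a median of 0.03 (adjusted p = 0.875), 1 lower member, calmodulin, and 2 higher and 5 lower adjusted over the list alone. Monoamine synthesis, breakdown and transport had a median of 0.08 (adjusted p = 0.189) and 1 higher member, ASMT,ASMTL. Heterotrimeric G protein signalling (median -0.06, adjusted p = 0.395) and immediate early genes (-0.16, 0.259) each had 1 called member. Oxidative stress and glutathione (median 0.08, adjusted p = 0.318) had 2 lower, both thioredoxins, and xenobiotic metabolism and efflux (-0.02, 0.752) had 1 lower, ABCC4. Extracellular matrix and its proteases (median 0.06, adjusted p = 0.303), innate immunity (0.00, 0.43) and lysosome and phagocytosis (0.05, 0.189) had 1 lower, 1 higher and 2 higher members.

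**Figure D3:**
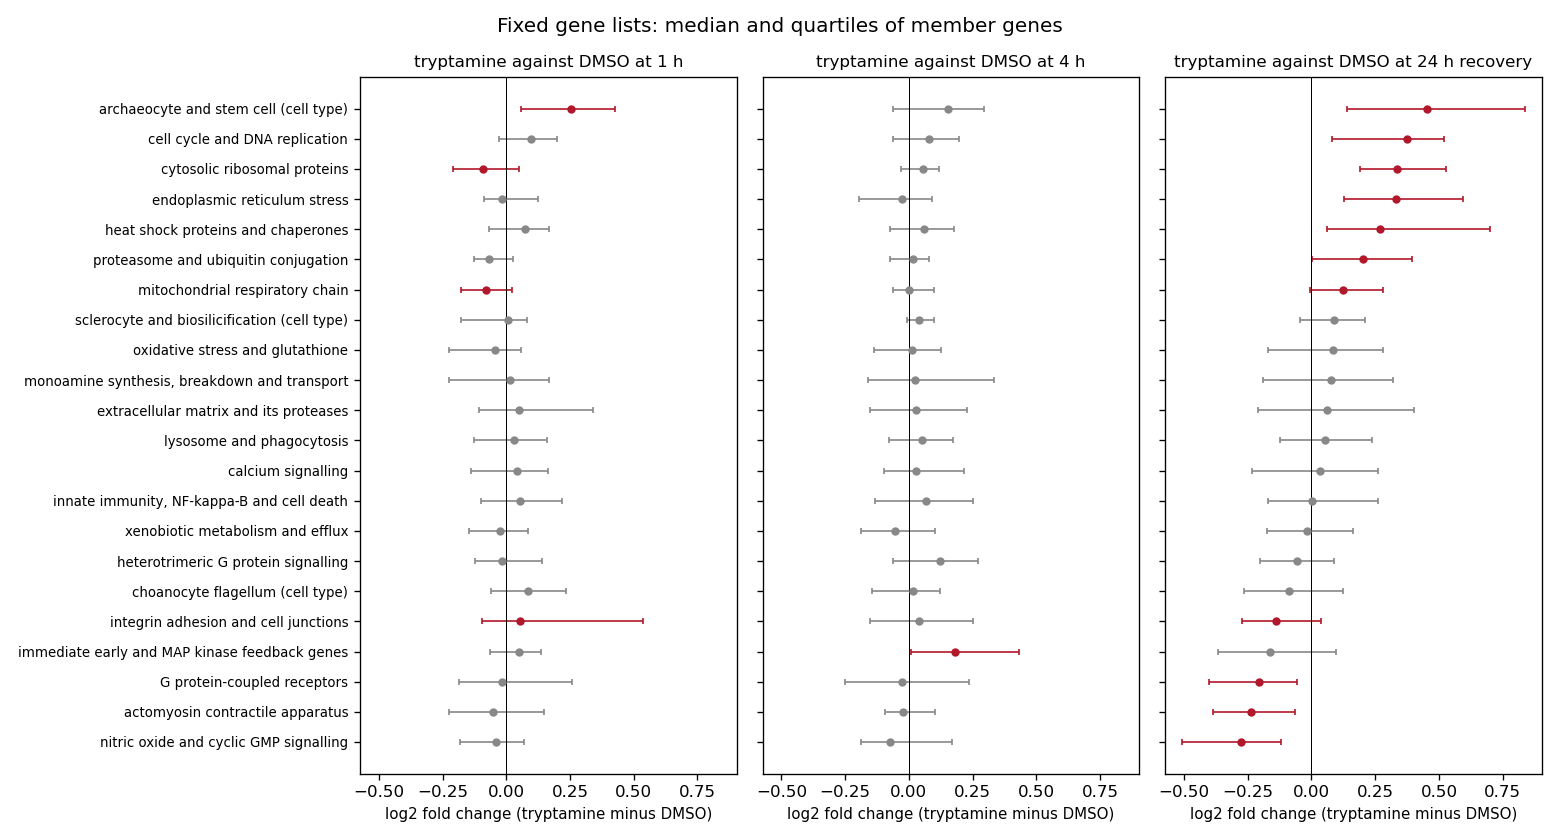
Median log2 difference, tryptamine minus DMSO, with quartiles over the tested members of each gene list shown, at 1 h, at 4 h and after recovery. Red marks camera adjusted p under 0.05 at the preset correlation, which 4, 1 and 11 lists reached.

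Whether the effect of tryptamine differed between times was tested by interaction contrasts. Between 4 h and 1 h, edgeR called 0 genes, with 994 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0527, while DESeq2 called 92, limma-voom 0, edgeR without a filter 11 and without robust dispersions 3. With the replicate block 4 genes were called, among them RSAD2 (-3.57, adjusted p = 0.0261) and CUL9 (-2.54, adjusted p = 0.0456), the latter named after its value was seen, and there were 90 without DMSO 4 h replicate 1 and 1 without tryptamine 4 h replicate 3. Between recovery and 4 h, 23 genes differed, all with a higher tryptamine minus DMSO difference after recovery than at 4 h, which is not a rise in level. DESeq2 called 180, limma-voom 0 and a fit of the compared groups alone 8. RSAD2 differed by 3.35 on the log2 scale (SE 0.48, adjusted p = 0.0223), with -3.34 at 4 h and 0.02 after recovery, and synoviolin by 2.84 (SE 0.43, adjusted p = 0.0238). The count of 23 was 0 without replicate 2 or 3 of DMSO at 4 h or of DMSO after recovery, and 1 without replicate 2 of tryptamine at 4 h or after recovery. It was 110 without DMSO 4 h replicate 1, 67 without tryptamine recovery replicate 1, 5 without DMSO recovery replicate 1, and 9 and 13 without tryptamine 4 h replicates 1 and 3.

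The DMSO groups alone give the background of time and handling. Several genes that were lower with tryptamine at 4 h were higher in DMSO at 4 h than at 1 h, with log2 changes of 3.86 (SE 0.35) for RSAD2, 5.19 (SE 0.54) for TRIM2 c87469-g1, 3.38 (SE 0.33) for synoviolin, 4.81 (SE 0.43) for RNF213 c94017-g2 and 1.66 (SE 0.23) for amine oxidase. The largest of their adjusted p was 0.000182, for amine oxidase. Between these times 678 genes rose and 253 fell in DMSO. The innate immunity list had 10 higher and 1 lower of 124, and 11 higher and 2 lower adjusted over the list alone, and the monoamine list 4 higher of 51 over all genes and adjusted over the list alone. Cell cycle and replication genes were shifted down (median -0.16, camera adjusted p = 8.99e-06, adjusted p = 0.708 with an estimated correlation). Of the 306 genes lower with tryptamine at 4 h, 260 were among the 678, where independent lists would share 8.6. Simulated unchanged groups shared 0, which sets no measure for this overlap, since they hold no changed gene to call. Both comparisons use the same 3 DMSO 4 h libraries, which cannot be divided into parts of at least 2 libraries each, so part of that overlap may come from the shared libraries. The correlation of fold changes across genes, which are not independent replicates, was -0.603 against -0.516 simulated, and the covariance -0.189 against -0.0695. The total of 931 was 591, 607 and 549 without DMSO 1 h replicates 1, 2 and 3, and 471 and 510 without DMSO 4 h replicates 2 and 3.

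From 4 h to the end of recovery 612 genes rose and 1044 fell in DMSO. This comparison uses the same DMSO recovery libraries as the tryptamine comparison after recovery, where ribosomal protein genes were shifted up. It uses the same DMSO 4 h libraries as tryptamine against DMSO at 4 h and as DMSO at 4 h against 1 h. Opposite changes in those comparisons are therefore not separate findings, and part of them may come from the shared libraries. Ribosomal protein genes were shifted down with 124 of 137 members negative and 8 lower, 5 adjusted over the list alone (median -0.33, camera adjusted p = 2.39e-08, adjusted p = 0.826 with an estimated correlation). Extracellular matrix genes were shifted down with 15 lower and 4 higher of 107, and 20 lower and 9 higher adjusted over the list alone (median -0.20, adjusted p = 0.0331, adjusted p = 0.826 with an estimated correlation). Cell cycle genes were shifted up with 8 higher of 101, and 9 adjusted over the list alone (median 0.13, adjusted p = 0.0331, adjusted p = 0.826 with an estimated correlation). In the innate immunity list 15 fell and 1 rose, and in the monoamine list 7 fell and 1 rose. The total of 1656 was 701 without DMSO 4 h replicate 2, and 708, 901 and 1027 without DMSO recovery replicates 1, 2 and 3.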

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

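The tests of the DMSO 4 h libraries, of reads from another organism, of the archaeocyte share and of the gene length trend were chosen after the data had been seen; the leaving out of single libraries after recovery and the regroupings of libraries were not. The effect of tryptamine differed between recovery and 4 h for 23 genes by the interaction test. Genes named by the rule among them included RSAD2 (3.35 on the log2 scale), synoviolin (2.84) and RNF213 c94017-g1 (3.54). Of 100 drawn regroupings of the libraries within each time, the real one included, 10 gave at least 23 genes. The 9 others each kept or exchanged the groups of 1 time whole, 8 of them those at 4 h. These draws still hold a treatment contrast, so the share cannot decide about chance, which stays open. The 79 draws that split both times gave at most 1 gene. The highest other draw, with 874 genes, split the 4 h groups and kept the recovery groups whole, so it too holds a treatment contrast. Whether a structure of the samples adds to its count was not tested.

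For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. At 4 h the real split gave 363 genes and the highest other 1, and after recovery 449 and 1. For DMSO at 4 h against 1 h the values were 931 and 0, and for DMSO recovery against 4 h 1656 and 0. In each of these 4 comparisons 1 split of the 10, the real one, reached its own count, and none of the 3 other splits that part every same-numbered pair called a gene at 4 h. At 1 h the real split gave 0 genes by edgeR (1553 at an unadjusted p under 0.05, 2 higher and 14 lower by DESeq2, 0 by limma-voom, 1 higher and 6 lower with the replicate block), and the highest other also 0. A count of 0 is reached by any regrouping, here by 10 of 10 at 1 h and by 100 of 100 for the effect at 4 h against that at 1 h, so it decides nothing about chance. The highest draw for the latter gave 266 genes and split the groups at both times, which points to a structure of the samples whose cause was not tested.

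The genes lower with tryptamine at 4 h stood above DMSO at 1 h mainly in DMSO at 4 h. Their median log2 difference was 2.09 there (303 of 306 genes above), 0.26 in tryptamine at 4 h and 0.38 in DMSO after recovery. Both 4 h groups selected these genes, which favours the gap between those groups. A single DMSO 4 h library is argued against, because genes called without one such library still stood above DMSO 1 h in that held-out library, with a lowest median of 1.3. Reads of an organism present only in the DMSO 4 h libraries are argued against too, because 98.4% of the genes had a count in every DMSO 1 h library, but one present at a low level at 1 h stays open. The 678 genes higher in DMSO at 4 h than at 1 h had a median of 0.77 in the tryptamine libraries, which share none with the selection. A rise of those genes was thus not confined to the DMSO libraries. The 306 genes themselves had a median of 0.50 in tryptamine (255 positive, 6 called) against 2.28 in DMSO. Whether their larger rise in DMSO was particular to the DMSO 4 h libraries was not decided by this. Of the 678 genes, with a median of 1.75 in DMSO, 635 changed less in tryptamine, and part of that may be selection. Selected the other way, 65 genes were higher in tryptamine at 4 h than at 1 h, with medians of 1.6 in tryptamine and 1.32 in DMSO. Of these 65, 27 changed more in DMSO. A hypothesis is that the genes lower with tryptamine at 4 h may have risen less with tryptamine between 1 h and 4 h. However, the interaction test called 0 genes in edgeR (994 at an unadjusted p under 0.05, 92 in DESeq2, 0 in limma-voom). It called 4 with the replicate block, among them RSAD2 (-3.57, edgeR adjusted p = 0.0261) and CUL9 (-2.54, adjusted p = 0.0456). Handling that differed between the 4 h groups as a whole stays open.

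The genes higher with tryptamine after recovery had a median log2 difference from DMSO 1 h of 0.48 in tryptamine recovery (0.456 to 0.49 per library). It was -0.34 in DMSO recovery (-0.421 to -0.214), where 13 of the 329 lay above DMSO 1 h. The same recovery libraries selected these genes, which favours the gap between them. The median of the 329 also lay above DMSO 1 h in tryptamine at 1 h (0.19, 301 genes) and at 4 h (0.14, 271 genes). The 3 tryptamine 1 h libraries had 0.507, 0.0931 and -0.0422, while single DMSO 1 h libraries ran from -0.165 to 0.19. A gene length trend as the whole cause is argued against: with it removed 241 genes were called higher, 236 of the 329 among them, and their median log2 change was 0.83 before and 0.798 after, with a median SE of 0.188 in both. Leaving out one library left 0 of the 329 called for 3 of the 6 libraries and 51, 72 and 180 for the others, 5 of the 6 thus ending most calls, while the median change stayed at 0.795 to 0.89 and the median adjusted p rose to between 0.0475 and 0.181, so dependence on one library and the loss of a sample could not be separated. A larger share of archaeocytes may account for part of the pattern, as their markers exceeded those of choanocytes by 0.538 in median. A change of expression within cells would give the same and was not separated from it. With a larger share, the lists of the other cell types were expected to fall alike. Neither the choanocyte nor the sclerocyte list was called after recovery, and the sclerocyte median was positive. The archaeocyte list holds 33 tested genes, 0 of them in another list, with a highest mean of 1120 CPM.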

How the results depend on the processing

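No named gene reversed direction under the alternatives run for it, nor did a called list under those run for lists (an estimated correlation, fry, median-of-ratios scaling, the replicate block and single libraries left out). Outside the leaving out of single libraries, named genes kept their call in 269 pairs of gene and setting at 4 h and lost it in 41, 18 of these in the fit without the 4 h libraries of number 2, and after recovery kept it in 320 and lost it in 40. Alternatives that moved a count of genes by more than 1.5 times are given here, and unless the construction shows it, the cause was not tested. With DESeq2 the higher and lower counts were 2 and 14 at 1 h and 782 and 335 after recovery, and 158 genes were higher at 4 h, with 92 genes differing between 4 h and 1 h and 180 between recovery and 4 h, where limma-voom gave 0. With the replicate block the counts were 1 and 6 at 1 h, 126 higher at 4 h, and 4 for 4 h against 1 h. After recovery the correlations were 0.0852 to 0.287, so 1 pair missed the bound of 0.1 and the rule for pairing was not met. Yet each was above the highest correlation of other pairs, 0.075, and 6 of 6 libraries were closest to their own number, so pairing there stays open. For DMSO recovery against 4 h the numbers did not pair the libraries (-0.161 to 0.0612, with 0 of 6). The replicate block gave 951 higher and 378 lower after recovery, 2603 for DMSO recovery against 4 h, and 39 for the effect after recovery against that at 4 h. The replicate block moved no other count by that much and changed no list count. A fit of the compared groups alone gave 31 higher at 4 h and 8 for recovery against 4 h, with fewer libraries to estimate the spread. For 4 h against 1 h, no filter gave 11 genes and no robust dispersion 3. Testing against a fold of 1.5 left 153 genes at 4 h, and after recovery a fold of 1.2 left 5 and a fold of 1.5 left 0, a stricter question by construction. Without the 4 h libraries of number 2, a choice made after seeing the data, 6 genes were higher and 92 lower at 4 h, with fewer samples. With an estimated correlation 0, 0 and 0 lists were called at 1 h, 4 h and recovery, and with fry 0, 0 and 4. Removing the length trend, also chosen later, left 70 and 284 at 4 h and 241 and 104 after recovery.

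Leaving out single libraries gave 0 to 0 higher and 0 to 5 lower at 1 h, 17 to 111 higher and 211 to 362 lower at 4 h, and 0 to 269 higher and 0 to 197 lower after recovery. The interaction counts ran from 0 to 90 for 4 h against 1 h and from 0 to 110 for recovery against 4 h, the DMSO counts from 471 to 1190 and from 701 to 1579, and the called lists from 1 to 6, 1 to 5 and 10 to 14. At 4 h, 13 of 31 named genes lost their call without at least 1 library, and after recovery 40 of 40. With 3 libraries a group, simulated 2-fold changes were recovered for 25.4% of genes at 4 h, so a gene that was not called may have changed by that much.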

Other observations

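The 4 gene groups described here were chosen after the results were seen, as was the comparison of the 4 h and recovery calls. Their tests therefore run on genes picked from the same data. Within each comparison their camera p-values were adjusted over these 4 groups alone. They cannot be set against those of the 23 fixed lists. After recovery, 50 of 100 ribosome biogenesis genes were higher with tryptamine and 0 lower, with 95 positive and a median log2 change of 0.77 (quartiles 0.576 to 0.904, camera adjusted p = 1.27e-53, adjusted p = 0.0344 with an estimated correlation). Examples were NOL6 (1.10, SE 0.24), NOP14 (1.02, SE 0.20) and TBL3 (1.04, SE 0.21), which process the small subunit's RNA, and FBL, fibrillarin, which methylates ribosomal RNA (0.93, SE 0.20). The same group had a median of 0.18 at 1 h with 0 genes called by edgeR (camera adjusted p = 8.81e-06, adjusted p = 0.496 with an estimated correlation). Of 25 cytosolic aminoacyl-tRNA synthetase genes, which load amino acids for translation, 9 were higher after recovery (median 0.56, camera adjusted p = 3.38e-12, adjusted p = 0.0692 with an estimated correlation).

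At 4 h, 18 of 77 genes picked as RNA-virus sensors and interferon-type effectors were lower with tryptamine and 0 higher, 7 of the 18 named RNF213. The median log2 change was -0.06 with 33 positive (quartiles -1.09 to 0.19, camera adjusted p = 4.32e-10, adjusted p = 0.0145 with an estimated correlation). The group was picked by symbol, so it also holds TRAF and STAT signalling genes and MOV10L1. Genes named TRAF2, TRAF3 and MOV10L1 were among the 18. From 1 h to 4 h in DMSO, 21 of the 77 rose and 1 fell, with a median of 0.41 (camera adjusted p = 0.00212 with an estimated correlation). In tryptamine the median of the 77 between these times was 0.08, with 44 positive and 0 called. The 18 genes lower at 4 h had a median of 0.80 in tryptamine, 17 of them positive, against 2.54 in DMSO. The selection of these 18 used both 4 h groups. After recovery 0 of the 77 differed by edgeR. The 77 genes carry 24 names, so near-identical copies weigh in these counts. Of 15 chitin synthase genes, which all carry 1 name, 5 were lower with tryptamine at 4 h (adjusted p = 0.0721 with an estimated correlation) and 6 rose in DMSO (adjusted p = 0.021 with an estimated correlation). Few genes were called at both 4 h and recovery: 5 were lower at both times, where independent lists would share 1.52, and 1 was higher at both (0.777), with 0 called in opposite directions (4.17 and 0.284). Of genes lower at 4 h, 67.3% had no usable name, against 61.3% of those tested and 18.5% of those higher after recovery.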
